A study of Mus musculus with 26 samples.

How the data were processed

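DNA methylation was measured by reduced representation bisulfite sequencing in 26 libraries of mouse cells, 2 libraries for each of 13 groups. Per the labels' protocols, genomic DNA was made into libraries with the NuGen Ovation RRBS Methyl-Seq system, converted with the Qiagen EpiTect Fast bisulfite kit and sequenced on an Illumina NovaSeq as single-end reads. Reads were trimmed with cutadapt and aligned with BSMAP to the mouse genome build mm9, per the submitters' processing notes. The versions and settings of both tools, and the caller of the CpG values, are not given in the sources used here.

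The authors deposited 1 table per library, with 1 line per CpG and both strands merged. Per the file headers, each line holds the count of all cytosine calls and the count of methylated calls, neither of them normalised, and the deposited methylation ratio is a fraction, the methylated calls divided by all calls of that CpG. These relations were checked in every line of every table. The strand counts summed to the totals in all 26 tables, and the ratio departed from the quotient by at most 0.0005. The tests used the counts, because a fraction alone does not carry its depth.

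The tables held between 3363523 and 3566126 CpGs and between 138889602 and 218879112 calls per library, with a median of 30 to 48 calls per CpG. CpGs were used when covered by at least 10 calls in all 26 libraries, which left 2299238 autosomal CpGs. Autosomes were divided into tiles of 500 bp, and a tile was tested when it held at least 3 such CpGs. The 232429 tested tiles had a median of 5 CpGs and 294 calls per library, with a 10th percentile of 106 calls and a 90th percentile of 1425 calls. Whether duplicate reads were removed by molecular identifiers was not established here, so calls may not be independent molecules. A precision computed from calls covers counting error only. The sex chromosomes and the mitochondrial genome were kept out of the main counts, because the groups differed in their sex chromosome signal. Unconverted calls on the mitochondrial genome ranged from 0.279 to 0.535% between libraries.

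Groups were taken from the sample labels. For each of 15 comparisons, the methylated and total calls of a tile were fitted with a quasi-binomial logistic model with 1 proportion per group. The dispersion was estimated from all 13 groups with 13 residual degrees of freedom, moderated by limma's empirical Bayes method (43.3 prior degrees of freedom, median dispersion 1.19, and at least 1), and used in an F test, which is two-sided. P-values were adjusted over all tiles of a comparison by the Benjamini-Hochberg method. A tile was called lower or higher at an adjusted p under 0.05 and a difference of group means of at least 10 percentage points. A group value is the mean of its 2 libraries, and its SD is that of the 2 libraries. The labels do not say whether the 2 libraries of a group came from separate cultures or animals, so the p-values measure only the spread between duplicate libraries, which may be technical. Between the 2 libraries of a group, the variance of CpG methylation was 1.03 to 1.10 times that of binomial sampling in all 13 groups. Its standard errors over CpGs were at most 0.00244. No pair was therefore treated as a copy of the same table. Such a ratio cannot tell the same library sequenced again from separate libraries.

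The interaction of doxycycline and FRG at Day 8, and the difference between the Day 4 and Day 8 effect of FRG given with doxycycline, were tested with limma on log2 ratios of methylated to unmethylated calls with 0.5 added to each. No untreated group later than Day 0 was among the labelled samples, so Day 0 was the untreated arm. Mean methylation weighted every CpG alike and was compared by two-sided exact permutation tests, which cannot go below p = 0.333 for 2 libraries against 2. Its relation to the day of treatment was tested over the 8 libraries of Day 0 and of Dox+FRG at Days 4, 8 and 10, without the Day 6 libraries. For a position between Day 0 and primary satellite cells, tiles called in that comparison with a difference of at least 20 points were used, and each library's mean over those tiles was scaled so that the Day 0 mean was 0 and the primary satellite cell mean 1. Standard errors over tiles came from a jackknife over the 19 autosomes. Overlaps of called tiles were set against the product of the list sizes divided by the tiles tested, and against the number for lists drawn at the same Day 0 level and CpG density. Because comparisons with Day 0 share their control libraries, unchanged groups were simulated against those libraries in 5 draws. Part of any excess overlap or correlation between such comparisons may come from the shared controls, since 2 control libraries cannot be split into pairs.

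The models were tested on simulated calls for the 232429 tiles of Dox+FRG Day 8 against Day 0. Of 200 tiles lowered by 10 points each, the quasi-binomial model called 32.5%, of those lowered by 20 points 92.5%, and of those lowered by 40 points 100.0%. It called 6 of 231829 unchanged tiles. For the interaction of doxycycline and FRG at Day 8, limma found 5.5%, 33.5% and 85.5% of tiles lowered by 10, 20 and 40 points, and called 12 unchanged tiles. The lowered tiles were drawn only from those at intermediate to high methylation at Day 0. The simulated spread was the one fitted to these duplicate libraries, so these rates do not cover variation between cultures or animals.

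The named tiles were chosen by a rule set before the data were examined, namely the called tiles with the largest decreases and increases in which both libraries of a group lay outside the range of the other group. The rule asked for 1 tile per gene, and a spacing of at least 10 kb stood in for that. For Dox+FRG Day 10 GFP and primary satellite cells against Day 0, 8 tiles in each direction were taken, and 3 in each direction elsewhere. Coordinates are those of mm9, counted from 1. No annotation or sequence of that build was used here, so tiles carry no gene names, and the tests of promoters, gene lists, motifs and genomic annotation that were foreseen were not run. Adjacent called tiles of the same direction within 1000 bp were joined into regions. Alternatives to these choices covered the coverage minimum, the tile length, the size threshold, chromosome X, the source of the dispersion, limma in place of the quasi-binomial model, the replicate number as a block, the weighting of CpGs and the removal of each library in turn. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 with limma 3.58.1.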

Results

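Methylation at CpGs was measured in mouse embryonic fibroblasts (MEFs) exposed to conditions for making induced muscle progenitor cells, and in satellite cells, the resident stem cells of skeletal muscle. Per the labels, the fibroblasts carried a doxycycline-inducible transgene for MyoD, a transcription factor that turns fibroblasts into muscle cells, and a nuclear GFP reporter of Pax7, a marker of satellite cells. Doxycycline (Dox) switches the transgene on. FRG is read here as forskolin, RepSox and the GSK3 inhibitor CHIR99021, the small molecules listed in the growth protocol. MEF14 cells were sampled untreated at Day 0, with Dox+FRG at Days 4, 8 and 10, with Dox alone at Days 4 and 8, with FRG alone at Day 8, and with Dox+FRG at Day 6 in normoxia or hypoxia (5% oxygen). The Day 10 group carries GFP in its name, and whether its cells were sorted is not stated. MEF10 cells were sampled at Day 6 of MyoD+FRG and of MN+FRG, a condition that the labels do not explain. How MEF10 and MEF14 cells differ is not explained either, and no untreated MEF10 group was among the samples. Primary satellite cells (primary SCs) came from adult mice with the Pax7 reporter, and expanded SCs were kept in culture. Each of the 13 groups had 2 libraries.

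Mean methylation over the 2299238 shared autosomal CpGs was 47.0% ± 0.0260 (SD, n = 2) at Day 0. It was 46.5% ± 0.0368 at Day 4, 45.6% ± 0.00552 at Day 8 and 45.6% ± 0.0393 at Day 10 of Dox+FRG (n = 2 each). Primary SCs had 43.4% ± 0.12 and expanded SCs 43.9% ± 0.0216. The single treatments lay above Day 0, with 47.3% ± 0.0440 for Dox Day 4, 47.5% ± 0.0660 for Dox Day 8 and 47.2% ± 0.0428 for FRG Day 8. Each of these 8 groups lay further from Day 0 than the SD of either group. The exact permutation test gave p = 0.333 for each of the 7 that were compared with Day 0, expanded SCs not being among them, the smallest that 2 libraries against 2 allow. Over the 8 Dox+FRG and Day 0 libraries, mean methylation fell with the day of treatment (Pearson's r = -0.981, exact permutation p = 0.00238, adjusted p = 0.00476; Spearman's rho = -0.878, exact permutation p = 0.0103, adjusted p = 0.0103, 2 coefficients). Without the 2 Day 0 libraries r was -0.949 (exact permutation p = 0.0667) and rho -0.717 (exact permutation p = 0.178), so the test was passed only with the Day 0 libraries. The 4 Dox+FRG Day 6 libraries were not part of this test, whose days were set before the data were examined; they had 46.2% ± 0.0157 in normoxia and 45.6% ± 0.0453 in hypoxia, the latter as low as Day 8 and Day 10. The 8 libraries were pairs of duplicates, which a permutation over libraries treats as separate. The Day 10 libraries are the GFP group, so a selection of cells, if made, cannot be told apart from the day. The means at Day 8 (45.62%) and Day 10 (45.60%) differed by less than the SD of Day 10. With calls pooled over CpGs instead of weighting each CpG alike, the Dox+FRG Day 4 difference from Day 0 changed from -0.524 to 0.352 points. The differences from Day 0 changed from -3.60 to -2.26 points for primary SCs, from 0.273 to 1.19 for Dox Day 4, from 0.429 to 1.14 for Dox Day 8 and from 0.128 to 0.477 for FRG Day 8.

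**Figure D1:**
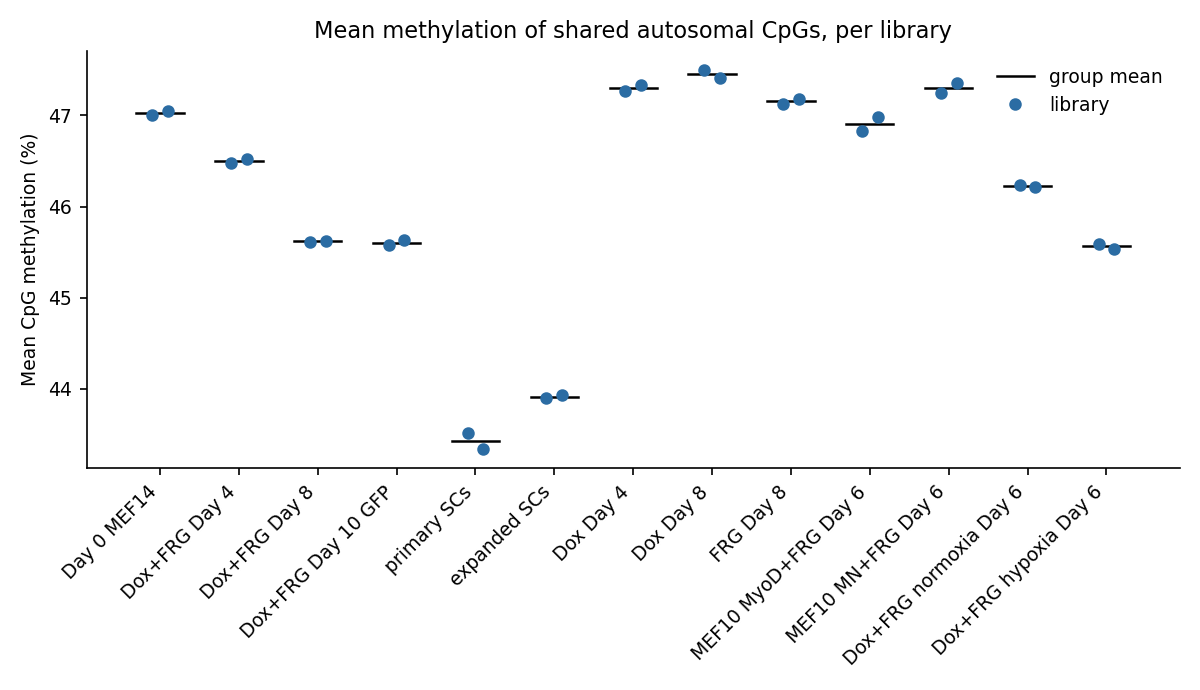
Mean methylation in percent of the shared autosomal CpGs on the vertical axis, which does not start at 0, for the 13 groups on the horizontal axis; points are libraries and lines are group means. The Dox+FRG groups lay below Day 0 (47.0%), with primary SCs lowest (43.4%) and Dox Day 8 highest (47.5%).

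The first comparisons followed Dox+FRG treatment from Day 0. At Day 4, 5917 of 232429 tiles were lower and 284 higher than at Day 0. At Day 8, 16782 were lower and 2088 higher, and in the Day 10 GFP group 21740 were lower and 5881 higher. Losses made up 95.4%, 88.9% and 78.7% of the calls at the 3 times. The median change of the lower tiles was -16.5, -17.4 and -18.4 points, and that of the higher tiles 12.7, 13.1 and 14.7 points. Of the lower tiles at Day 4, 4789 (80.9%) were also lower at Day 10, and of those at Day 8, 12804 (76.3%). Independent lists of these sizes would share 553.4 and 1570 tiles, and lists matched on Day 0 level and CpG density 1185 and 2987. The 5917 tiles lower at Day 4 had 59.9% ± 0.16 at Day 0, 40.7% ± 0.0451 at Day 4, 32.0% ± 0.0351 at Day 8 and 32.9% ± 0.11 at Day 10 (SD, n = 2).

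The mean loss per tile was largest at intermediate methylation. For Dox+FRG Day 8, tiles at 50 to 70% at Day 0 fell by 4.40 ± 0.0986 points (SE over 19 autosomes, 24383 tiles), against 2.36 ± 0.0748 points for tiles at 70 to 90%, 1.60 ± 0.0382 points for tiles at 90 to 100% and 0.191 ± 0.00854 points for tiles under 10%. By number, the largest group of lower tiles lay at 70 to 90% (7206), followed by 50 to 70% (4477) and 30 to 50% (2737). Tiles with 3 to 5 CpGs were lower in 9.33% of cases, and tiles with 21 to 40 CpGs in 0.241%. The former had a mean of 73.0% at Day 0 and the latter 28.1%. A tile under 10% at Day 0 cannot fall by the 10 points asked for, so these shares do not separate CpG density from starting level. At Day 10, 27.97% of the tiles at 30 to 50% were lower and 14.99% higher.

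At Day 10 the 8 named tiles with the largest losses had between 86.9 and 93.7% at Day 0 and at most 4.23% at Day 10. The tile at chromosome 11, 5101501 to 5102000 (6 CpGs, 339 to 712 calls per library) went from 93.7% ± 0.872 to 1.86% ± 0.541 (SD, n = 2; adjusted p = 3.07e-41, quasi-binomial test). It stood at 83.9% at Day 4 and 35.1% at Day 8, and at 91.7% in FRG Day 8. The tile at chromosome 6, 72094501 to 72095000 went from 88.4% ± 2.97 to 1.14% ± 0.358 (adjusted p = 4.23e-35, quasi-binomial test). In primary SCs all 8 of these tiles lay at 18.9% or lower. Among the gains, the tile at chromosome 17, 86091001 to 86091500 (14 CpGs, 416 to 874 calls) rose from 20.0% ± 1.14 to 80.5% ± 0.825 (adjusted p = 2.50e-31, quasi-binomial test), and primary SCs had 76.4% there. The tile at chromosome 4, 88923001 to 88923500 rose from 16.1% ± 0.0424 to 67.4% ± 3.61 (adjusted p = 1.21e-11), while primary SCs had 11.7%; the other 7 gained tiles had 50.04 to 93.4% in primary SCs. The largest loss at both Day 4 and Day 8 was at chromosome 18, 61540001 to 61540500 (4 CpGs, 247 to 469 calls), which had 83.2% ± 1.06 at Day 0, 7.87% ± 2.03 at Day 4 and 1.94% ± 1.31 at Day 8 (adjusted p = 3.93e-30 and 9.53e-34, quasi-binomial test). Of the Day 10 losses, 88.1% of 19077 regions were single tiles, and one of those with the most tiles, at chromosome 4 from 137039501 to 137044500, fell from 38.1% ± 0.628 to 4.96% ± 0.395 over 6 tiles. With limma on log2 ratios in place of the quasi-binomial model, the Day 4 comparison gave 3748 tiles instead of 6201.

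**Figure D2:**
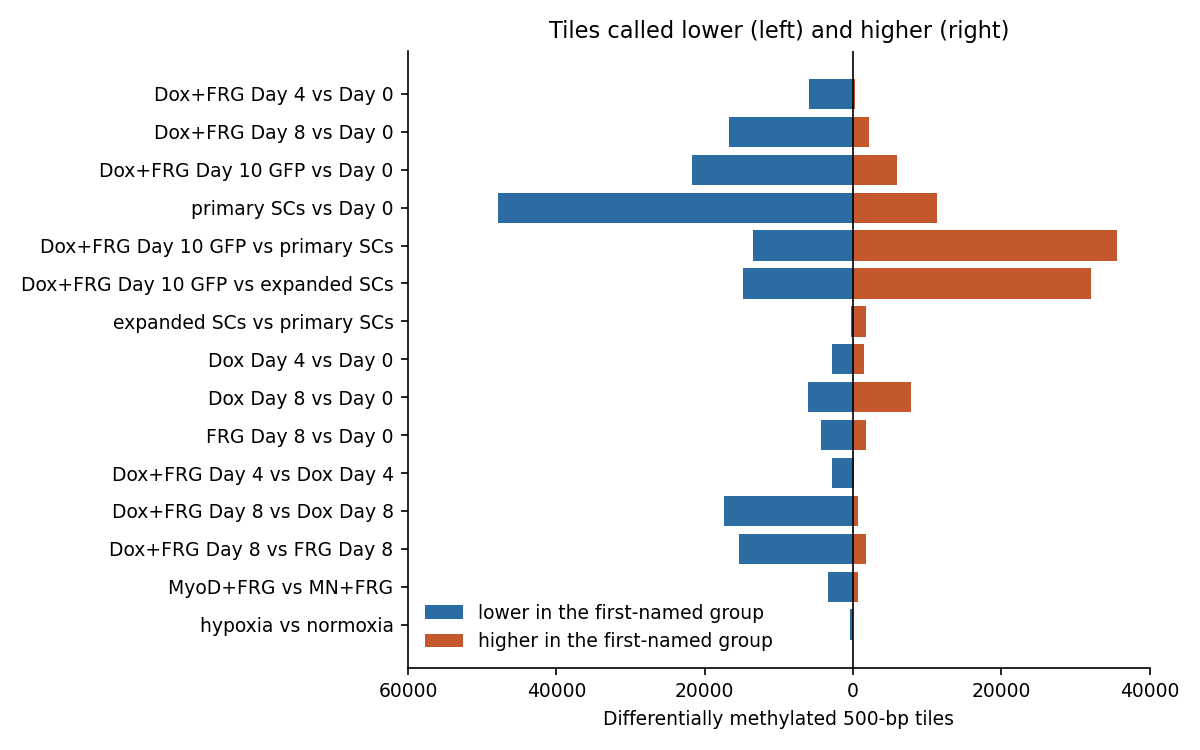
Number of 500-bp tiles called lower (bars to the left) or higher (bars to the right) in the first-named group of each of the 15 comparisons. The longest bar is the 47855 tiles lower in primary SCs than at Day 0, and hypoxia against normoxia gave 446 lower and 23 higher tiles.

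The second set of comparisons placed the treated fibroblasts relative to satellite cells. Primary SCs were lower than Day 0 at 47855 tiles and higher at 11278, with median changes of -20.4 and 17.8 points. Dox+FRG Day 10 GFP was lower than primary SCs at 13564 tiles and higher at 35592, and against expanded SCs it was lower at 14893 and higher at 32135. Of the 21740 tiles lower at Day 10, 15219 (70%) were also lower in primary SCs, and of the 5881 higher tiles 3162 (53.8%) were also higher. Opposite changes were seen at 924 tiles lower at Day 10 and higher in primary SCs and at 741 tiles with the reverse. Independent lists would share 4476 lower and 285.4 higher tiles, and lists matched on Day 0 level and density 7012 and 1025. Across tiles, which are not independent replicates, the changes from Day 0 at Day 10 and in primary SCs correlated at 0.555. Their covariance was 73.1 squared points. Unchanged groups simulated against the same Day 0 libraries gave 0.474 and 3.21. Those groups vary by error alone, so their correlation is no reference for groups that changed.

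Over 24498 tiles lower in primary SCs by at least 20 points, Day 0 was set to 0 and primary SCs to 1. On that scale Dox+FRG lay at 0.115 ± 0.0024 at Day 4, 0.262 ± 0.000058 at Day 8 and 0.354 ± 0.0035 at Day 10, and expanded SCs at 0.919 ± 0.00072 (SD, n = 2). Dox Day 8 lay at 0.0667 ± 0.0042 and FRG Day 8 at 0.0360 ± 0.0023. The tiles were picked on the same libraries that set 0 and 1, so small positions can come from that choice. Every other group lay above 0 here, MEF10 MN+FRG at 0.0568 ± 0.0111. Over the 4671 tiles higher by at least 20 points, Dox+FRG lay at -0.0254 ± 0.0029 at Day 4, 0.0663 ± 0.0034 at Day 8 and 0.240 ± 0.0038 at Day 10. The Day 4 value became -0.0474 when tiles were picked on replicate 1 and measured against replicate 2. Dox Day 8 reached 0.263 ± 0.0049 over the 4671 tiles, above Dox+FRG at the same day. Of the 24498 tiles, 11357 (46.4%) were lower at Day 10 than at Day 0, 4326 (17.7%) were lower and no longer called apart from primary SCs, and 19588 (79.96%) were still called apart from them. A tile not called apart can still differ by less than the test could find. Of the 4671 higher tiles, 1852 (39.6%) had gained by Day 10, 737 (15.8%) had gained and were not called apart, and 3882 (83.1%) were called apart.

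**Figure D3:**
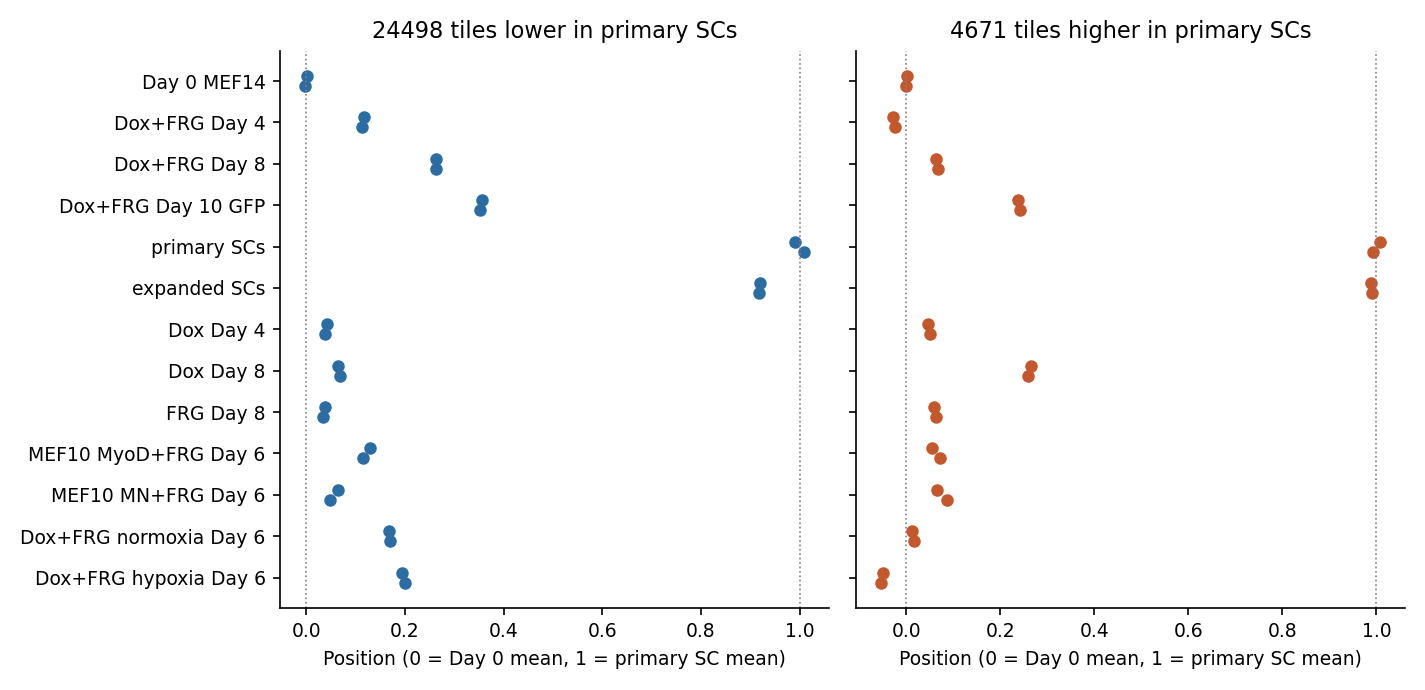
Position of each library (points) on the horizontal axis, a scale without unit on which the Day 0 mean is 0 and the primary SC mean 1, for the 13 groups on the vertical axis; the left panel has the 24498 tiles lower and the right panel the 4671 tiles higher in primary SCs. Dox+FRG Day 10 GFP lay at 0.354 in the left panel and 0.240 in the right.

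The 8 named tiles with the largest losses in primary SCs had at least 93.1% at Day 0 and at most 3.85% in primary SCs. The tile at chromosome 4, 8793001 to 8793500 (18 CpGs, 334 to 952 calls) had 95.1% ± 0.0539 at Day 0 and 3.16% ± 1.75 in primary SCs (SD, n = 2; adjusted p = 3.66e-43, quasi-binomial test), 6.7% in expanded SCs and 90.9% in Dox+FRG Day 10 GFP. The tile at chromosome 13, 74494001 to 74494500 (9 CpGs) had 94.5% ± 1.32, 2.08% ± 0.535 and, at Day 10, 95.6% (adjusted p = 3.34e-43 for primary SCs against Day 0, quasi-binomial test). At Day 10, 6 of the 8 tiles had 85.1 to 96.3%, and the others 70% and 56.2%. Among gains, the tile at chromosome 7, 144507001 to 144507500 (30 CpGs, 1060 to 2721 calls) had 11.2% ± 0.137 at Day 0, 87.6% ± 0.0764 in primary SCs (adjusted p = 5.96e-46, quasi-binomial test) and 31.1% at Day 10. The tile at chromosome 18, 75532501 to 75533000 had 10.7% ± 1.11 at Day 0, 93.4% ± 0.223 in primary SCs (adjusted p = 6.28e-32, quasi-binomial test) and 59.99% ± 2.77 at Day 10. The region lower in primary SCs with the most tiles, at chromosome 3 from 137728001 to 137733500, held 10 tiles and had 81.9% ± 0.0013 at Day 0, 5.51% ± 0.872 in primary SCs and 61.4% ± 1.44 at Day 10. The region higher in primary SCs with the most tiles, at chromosome 10 from 84215501 to 84223000, had 14.5% ± 0.594 at Day 0, 57.5% ± 0.276 in primary SCs and 23.4% ± 2.25 at Day 10. The groups also differed on chromosome X, which these counts leave out: 174 X tiles with 41 CpGs or more had 21.6% ± 0.0272 at Day 0 and 3.08% ± 0.0272 in primary SCs, against 1.39% and 1.51% on autosomes.

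Expanded SCs differed from primary SCs at few tiles, 291 lower and 1762 higher. The 1762 higher tiles had 32.3% ± 0.90 in primary SCs, 46.6% ± 0.0651 in expanded SCs and 64.8% ± 0.11 at Day 0 (SD, n = 2), and because they were picked for low values in primary SCs, the difference from these can be overstated. The largest loss on expansion was at chromosome 9, 63591501 to 63592000 (9 CpGs, 250 to 610 calls), from 80.8% ± 2.78 to 27.2% ± 1.07 (adjusted p = 1.39e-21, quasi-binomial test), and this tile had 55.8% at Day 0. At chromosome 14, 9632501 to 9633000, methylation rose from 50.04% ± 5.57 to 90.7% (adjusted p = 6.38e-13). The 2053 calls became 1250 with limma, 1191 with the dispersion of the 4 compared libraries alone, 1281 when 3 or more CpGs had each to move by 10 points the same way, and 1232 without primary SC replicate 2.

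The third set of comparisons looked at Dox and FRG given alone and together. Against Day 0, Dox alone was lower at 2906 tiles and higher at 1410 at Day 4, and lower at 6035 and higher at 7764 at Day 8. At a difference of at least 20 points Dox Day 8 was lower at 2329 and higher at 1065, so which direction was more frequent turned with the size asked for. FRG Day 8 was lower than Day 0 at 4321 tiles and higher at 1686. Without an untreated group of the same day, these changes cannot be told apart from time in culture. Dox Day 8 and FRG Day 8 shared 1777 lower and 694 higher tiles, where matched lists would give 244.2 and 242.7. Time in culture and the shared Day 0 libraries may each add to this overlap. Tiles at 10 to 30% at Day 0 gained 3.39 ± 0.113 points in Dox Day 8 (SE over 19 autosomes, 10937 tiles) and 0.584 ± 0.0823 in FRG Day 8, and fell by 2.11 ± 0.117 in Dox+FRG Day 8. Compared directly, Dox+FRG Day 4 was lower than Dox Day 4 at 2842 tiles and higher at 109. Dox+FRG Day 8 was lower than Dox Day 8 at 17396 and higher at 595, and it was lower than FRG Day 8 at 15402 and higher at 1784.

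**Figure D4:**
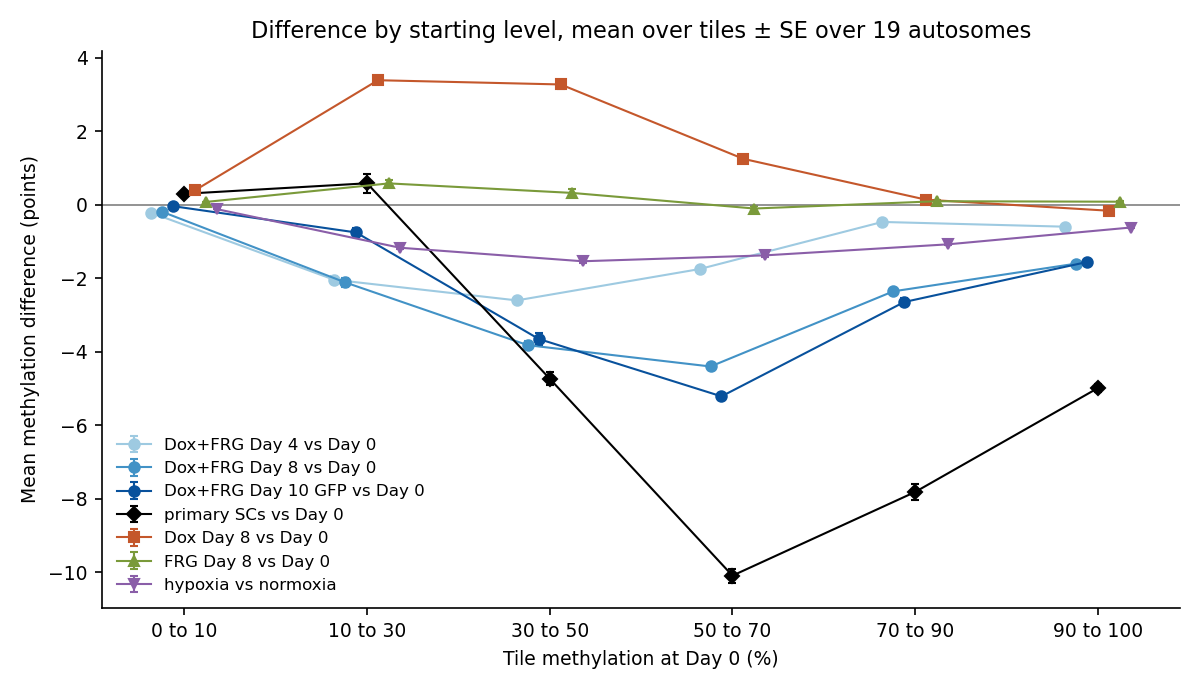
Mean methylation difference in percentage points on the vertical axis against the tile's methylation at Day 0 in percent on the horizontal axis, for 7 comparisons; bars are standard errors over 19 autosomes. Dox Day 8 lay above 0 at 10 to 30% (3.39 points) where Dox+FRG Day 8 lay below it, and primary SCs had their largest mean loss at 50 to 70%.

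Most tiles lower in Dox+FRG Day 8 passed the test in neither single treatment. Of the 16782 tiles, 1722 (10.3%) were also lower in both Dox Day 8 and FRG Day 8, 3419 (20.4%) in Dox Day 8 only, 1554 (9.26%) in FRG Day 8 only and 10087 (60.1%) in neither. The 10087 tiles had 65.8% ± 0.0628 at Day 0, 63.6% ± 0.116 in Dox Day 8, 64.7% ± 0.135 in FRG Day 8 and 49.1% ± 0.111 in Dox+FRG Day 8 (SD, n = 2). Compared directly, Dox+FRG Day 8 was lower than Dox Day 8 at 6652 of them, lower than FRG Day 8 at 7319 and lower than both at 5422. In primary SCs they had 42.8% ± 0.329. The classes were sorted by calls in these same treated and Day 0 libraries. Levels near Day 0 in the single treatments are therefore partly fixed by the sorting, and the direct comparisons used the same treated libraries again. The changes of Dox+FRG Day 8 and Dox Day 8 had a covariance of 25.5 squared points, against 3.21 in simulated unchanged groups. Those of Dox+FRG Day 8 and FRG Day 8 had 15.8, against 3.23. The correlations across tiles were 0.642 and 0.482, against 0.473 and 0.480. Unchanged groups vary by error alone, which they share through the Day 0 libraries, so their correlations are no reference for groups that changed.

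**Figure D5:**
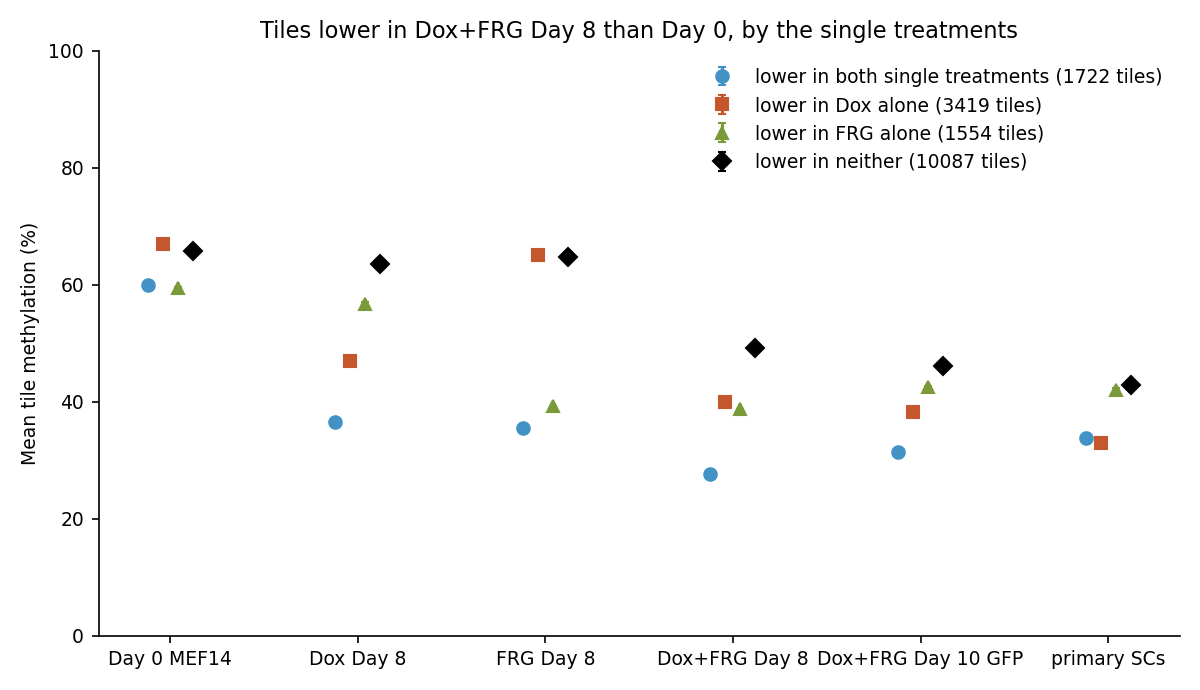
Mean tile methylation in percent (vertical axis) in 6 groups (horizontal axis) for the 16782 tiles lower in Dox+FRG Day 8 than at Day 0, divided by whether Dox Day 8 and FRG Day 8 were also called lower; points are means and bars, mostly hidden by the points, are SDs of 2 libraries. The 10087 tiles called in neither had 63.6% in Dox Day 8, 64.7% in FRG Day 8 and 49.1% in Dox+FRG Day 8. Because the classes were made from calls in these libraries, such levels are partly fixed by the sorting.

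The interaction was tested directly, with Day 0 in place of an untreated Day 8 group. A change with time in culture would therefore also enter this contrast, which cannot tell it from an interaction. At 12740 tiles Dox+FRG Day 8 lay below, and at 1359 above, what the single treatments add up to on the log2 scale (limma, adjusted p under 0.05). The median departure was -14.8 points at the former and 19.2 at the latter. The effect of FRG given with Dox was more negative at Day 8 than at Day 4 at 2051 tiles and more positive at 164. Leaving out single libraries gave 7340 to 9455 tiles in place of 14099 for the interaction, and 727 to 1045 in place of 2215 for the difference between days.

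Tiles differed in which treated group departed most from Day 0. At chromosome 3, 52341501 to 52342000 (203 to 338 calls), methylation was 74.8% at Day 0, 82.9% ± 5.76 in FRG Day 8, 11.8% in Dox Day 8 and 0.617% ± 0.429 in Dox+FRG Day 8 (adjusted p = 6.66e-32 for Dox+FRG against FRG, quasi-binomial test). At chromosome 11, 120544001 to 120544500 (4 CpGs, 268 to 503 calls), it was 87.1% ± 1.19 at Day 0, 40.03% in Dox Day 8, 5.82% ± 0.920 in FRG Day 8 (adjusted p = 1.92e-32, quasi-binomial test) and 26.1% in Dox+FRG Day 8. The tile with the largest difference between Dox+FRG and Dox at Day 8, at chromosome 13, 53163001 to 53163500, had 55.9% at Day 0, 73.7% ± 0.759 in Dox Day 8, 48.3% in FRG Day 8 and 5.91% ± 1.37 in Dox+FRG Day 8 (adjusted p = 9.92e-20, quasi-binomial test). The largest gain in Dox Day 8, at chromosome 10, 122281501 to 122282000, went from 23.5% ± 6.07 to 73.1% ± 13.7 (44 to 136 calls; adjusted p = 2.54e-07, quasi-binomial test). At chromosome 16, 95930001 to 95930500 (11 CpGs, 865 to 1524 calls), Dox+FRG Day 4 had 20.7% ± 1.41 against 69.2% ± 4.06 in Dox Day 4 (adjusted p = 2.05e-30, quasi-binomial test), and FRG Day 8 had 4.5%. With limma in place of the quasi-binomial model, Dox Day 4 against Day 0 gave 1589 tiles instead of 4316, FRG Day 8 against Day 0 3439 instead of 6007, and Dox+FRG Day 4 against Dox Day 4 999 instead of 2951.

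In MEF10 cells, MyoD+FRG was compared with MN+FRG at Day 6. MyoD+FRG was lower at 3363 tiles and higher at 727, with median changes of -16.3 and 16.1 points. Of the lower tiles, 2895 (86.1%) were also lower in MEF14 Dox+FRG Day 8 than at Day 0, a comparison that shares no library with this one, where matched lists would give 430.5. Of the same tiles, 323 (9.60%) were lower in FRG Day 8, 1478 (43.9%) in Dox Day 8 and 2535 (75.4%) in primary SCs than at Day 0, where matched lists would give 120.2, 157.8 and 1043. The 3363 tiles had 48.1% ± 0.59 in MyoD+FRG and 66.4% ± 0.46 in MN+FRG, against 69.1% ± 0.0480 at Day 0 of MEF14, 67.5% ± 0.12 in FRG Day 8 and 43.9% ± 0.0310 in Dox+FRG Day 8 (SD, n = 2). The largest difference was at chromosome 10, 68671001 to 68671500 (4 CpGs, 46 to 151 calls), with 15.4% ± 1.79 in MyoD+FRG and 83.0% ± 4.64 in MN+FRG (adjusted p = 5.14e-14, quasi-binomial test), a tile that was also the largest loss of Dox+FRG Day 10 GFP. Of the 727 tiles higher in MyoD+FRG, 333 (45.8%) were lower in Dox+FRG Day 8, 23 were higher in Dox+FRG Day 8 and 194 (26.7%) were lower in FRG Day 8 than at Day 0, where matched lists would give 102.1, 17.3 and 29.8. At chromosome 5, 101221001 to 101221500, MyoD+FRG had 59.0% ± 0.153 and MN+FRG 8.36% ± 0.941 (adjusted p = 1.21e-13, quasi-binomial test), and MEF14 had 77.2% at Day 0 and 7.0% in FRG Day 8. Across tiles, which are not independent replicates, the difference correlated with the change of Dox+FRG Day 8 at 0.353, with that of Dox Day 8 at 0.197 and with that of FRG Day 8 at 0.0119, and differences between these correlations were not tested. With limma, 2598 tiles were called instead of 4090.

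The last comparison asked what low oxygen changed under Dox+FRG at Day 6. Hypoxia was lower than normoxia at 446 tiles and higher at 23, the smallest count of the 15 comparisons. The 446 tiles had 51.6% ± 0.0154 in normoxia and 36.4% ± 0.36 in hypoxia, against 67.0% ± 0.17 at Day 0, 45.2% ± 0.11 in Dox+FRG Day 8 and 49.5% ± 0.15 in FRG Day 8 (SD, n = 2). Of them, 331 (74.2%) were lower in Dox+FRG Day 8, 270 (60.5%) in FRG Day 8 and 207 (46.4%) in Dox Day 8 than at Day 0, where matched lists would give 61.5, 17.4 and 22.4. Mean methylation was 45.6% ± 0.0453 in hypoxia and 46.2% ± 0.0157 in normoxia (exact permutation p = 0.333, the smallest possible). The largest decrease was at chromosome 17, 56341501 to 56342000 (40 to 112 calls), from 89.96% ± 6.0 to 53.8% ± 6.17 (adjusted p = 3.25e-04, quasi-binomial test). At chromosome 14, 32483001 to 32483500 (6 CpGs, 95 to 317 calls), hypoxia had 33.6% ± 0.732 and normoxia 66.0% ± 8.25 (adjusted p = 0.00302, quasi-binomial test). The count depended on how the spread was estimated: 2 tiles were called with the dispersion of the 4 compared libraries and 69 with limma, and leaving out normoxia replicate 1, normoxia replicate 2, hypoxia replicate 1 or hypoxia replicate 2 gave 205, 276, 256 and 175. With calls pooled over CpGs the mean difference changed sign, from -0.664 to 0.0662 points.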

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

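The tests of sequence variants, bisulfite conversion, sex, dilution and summed treatments, and their settings, were chosen only after the results they bear on had been seen; the tests of the 2 limma contrasts were set before the data were examined.

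The 2 limma contrasts differed between treatment arms. Dox+FRG Day 8 lay below the sum of the single treatments at 12740 tiles and above it at 1359, and the effect of FRG given with Dox was more negative at Day 8 than at Day 4 at 2051 tiles and more positive at 164. Of the 2 technical or trivial explanations considered for the excess loss, the first is dilution of methylation by cell division. At the same rate in all tiles, it calls for losses in proportion to the level. In Dox+FRG Day 8 against Dox Day 8, tiles at 90% or more had a low proportional loss. It was only 0.173 ± 0.0055 (SE) of that of tiles at 50 to 70%. That argues against dilution at the same rate everywhere as the whole cause. Dilution at rates that differ between tiles stays open. The other explanation is a plain sum of the single treatments. Over all tested tiles the summed mean change from Day 0 was 0.675 points and the observed one -2.12, with a largest group SD of 0.093 points. A change with time in culture would enter the sum with each single treatment, and so count more there than in the observed change. Without an untreated Day 8 group these values cannot decide whether the treatments add up. At the 16782 tiles lower in Dox+FRG Day 8 the summed changes, -8.10 points for Dox and -5.43 for FRG, reached 0.651 of the observed -20.8, so an additive part stays open there. Those tiles were called on the same Dox+FRG Day 8 and Day 0 libraries. That choice can overstate the observed change, and the error of Day 0 enters both single changes. An effect of the 2 treatments on each other may remain as a hypothesis, and time in culture, for which no untreated Day 8 group was analysed, was not tested.

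Primary SCs stood far below Day 0, with 47855 lower tiles. Sequence variants between mouse strains remove single CpGs, yet 89.9% of the tiles lower by at least 20 points had 3 or more CpGs that were each lower by at least 10 points, which argues against them as the main cause. Over all 47855 lower tiles this share was 70.7%, and 6.96% had at most 1 such CpG. Incomplete conversion at Day 0 is argued against by the mitochondrial genome. There the methylated share was 0.138 points higher in primary SCs than at Day 0, the larger group SD being 0.061 points. Sex as the whole cause is argued against by the MEF10 fibroblasts, whose chromosome Y signal was near that of primary SCs, while their larger position over the 24498 tiles, that of MyoD+FRG, was 0.123 ± 0.0095 (SD, n = 2), where primary SCs are at 1. Age and tissue of the source animals, which go along with the cell type, were not tested and may each contribute, as may sex in part.

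Calls on chromosome Y stood out in data the comparisons left out. They came to 572.6 ppm of all calls in MEF10 MyoD+FRG, 585.3 in MEF10 MN+FRG, 617.6 in primary SCs and 593.3 in expanded SCs (means of 2 libraries), against 268.6 at Day 0 of MEF14. Mitochondrial calls were highest in hypoxia, with 924.1 ppm of all calls against 809.4 ± 52.1 in normoxia and 503.9 ± 26.5 at Day 0 (SD, n = 2).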

How the results depend on the processing

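One alternative was chosen after seeing the data, the demand that 3 or more CpGs of a tile each move by 10 points the same way; all others were set before. All 15 counts of called tiles stayed within 1.5 times with a coverage minimum of 5 or 20, tiles of 1000 bp and chromosome X added. The libraries share only a replicate number: deviations of same-numbered libraries correlated at -0.0135 to 0.0199 over 78 pairs of groups, and with the replicate number as a block all 15 counts and both interactions were within 1.5 times (for example 18870 tiles without and 18852 with the block for Dox+FRG Day 8 against Day 0).

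Fewer tiles were called, by construction, at a difference of 20 points: 2053 for Dox+FRG Day 4, 6804 for Day 8, 10866 for Day 10 and 29169 for primary SCs against Day 0, 21869 for Day 10 against primary and 20081 against expanded SCs, 248 for expanded against primary SCs, 1025 for Dox Day 4, 3394 for Dox Day 8 (2329 lower and 1065 higher, against 6035 and 7764 at 10 points) and 1756 for FRG Day 8 against Day 0, 623, 3778 and 5153 for Dox+FRG against Dox Day 4, Dox Day 8 and FRG Day 8, 1263 for MyoD+FRG against MN+FRG and 67 for hypoxia. With limma, Dox+FRG Day 4 gave 3748, Dox Day 4 1589, FRG Day 8 3439, Dox+FRG against Dox Day 4 999, MyoD+FRG 2598, expanded SCs 1250 and hypoxia 69; with the dispersion of the 4 compared libraries, expanded SCs gave 1191 and hypoxia 2; with 3 CpGs required, expanded SCs gave 1281. For these changes the cause was not tested.

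Leaving out single libraries gave 1232 to 1562 tiles for expanded SCs (1232 without primary SC replicate 2), 175 to 276 for hypoxia, 7340 to 9455 for the Dox and FRG interaction (lowest without Day 0 replicate 2) and 727 to 1045 for the difference between days (lowest without Dox Day 4 replicate 1), where the group with 1 library was assumed to vary like the others. With calls pooled over CpGs the mean differences of Dox+FRG Day 4 (0.352 points) and hypoxia (0.0662) reversed, 12 others moved by more than the replicate SD and 1 did not. Those that moved by more than 1.5 times became -2.26 for primary SCs, 1.19 for Dox Day 4, 1.14 for Dox Day 8 and 0.477 for FRG Day 8 against Day 0, 1.19 and 0.832 for Dox+FRG Day 10 against primary and expanded SCs, -2.82 for Dox+FRG Day 8 against Dox Day 8 and -0.780 for MyoD+FRG against MN+FRG. The cause was not tested. Of 22 positions, 15 moved by at least the replicate SD and 1 reversed when tiles were picked on replicate 1 and measured against replicate 2. At 40 points 18 of 22 moved. The position of Dox+FRG Day 10 was 0.358 for lower tiles at a coverage minimum of 20, and for higher tiles 0.229 when picked on replicate 1 and measured against replicate 2 and 0.246 at 40 points. For the higher tiles, picking on replicate 1 moved Dox+FRG Day 4 from -0.0254 to -0.0474 and reversed normoxia from 0.0151 to -0.00529, and at 40 points hypoxia moved from -0.0506 to -0.0295. Of 1364 values of named tiles, 57 lost the call and 0 reversed; at a minimum of 20 calls 44 of the 110 could be evaluated. Alternatives for promoters and gene lists were not run, as no annotation of mm9 was used. Of simulated losses of 10 points, 49.5% passed the adjusted p and 32.5% were called, since the minimum difference was also 10 points.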

Other observations

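The tests of hypoxia against a conversion difference were chosen only after the result was seen; the test of a faster course was set before its result was seen.

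Across tiles, which are not independent replicates, the difference between hypoxia and normoxia correlated at 0.150 with the change of FRG Day 8, at 0.0954 with that of Dox+FRG Day 4, at 0.0368 with that of Dox+FRG Day 8 and at 0.0163 with that of Dox Day 8; differences between these correlations were not tested. On the scale from Day 0 to primary SCs, hypoxia lay at 0.197 ± 0.0044 and normoxia at 0.169 ± 0.0013 over the lower tiles (SD, n = 2), and over the higher tiles at -0.0506 ± 0.0033 and 0.0151 ± 0.0031. Over the higher tiles these became -0.0749 and -0.00529 when tiles were picked on replicate 1 and measured against replicate 2, and -0.0295 and 0.0206 at a difference of at least 40 points. Some tiles moved away from primary SCs. At chromosome 17, 27904501 to 27905000, methylation was 81.8% at Day 0, 6.65% at Day 4 of Dox+FRG, 23.0% at Day 10, 1.46% in FRG Day 8 and 94.8% in primary SCs.

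The fall in hypoxia was weighed against 2 explanations. Excess conversion in hypoxia would remove methylated calls in one proportion. The proportional loss of tiles at 90% or more was 0.290 ± 0.012 (SE) of that of tiles at 50 to 70%, which argues against it. Incomplete conversion in normoxia would not follow that rule, but would leave more unconverted mitochondrial calls. These were 0.301% ± 0.018 in normoxia and 0.289% ± 0.012 in hypoxia (SD, n = 2), which argues against that form. A faster course of the same Dox+FRG change would raise the tiles higher at Day 8 than at Day 0. Over these tiles hypoxia minus normoxia was -2.67 points, the larger group SD being 0.082 (n = 2). That argues against a course sped up for gains and losses alike. Few tiles (284) had gained by Day 4, so a faster loss alone stays open. Of the 446 tiles lower in hypoxia, 291 were lower than Day 0 in Dox+FRG Day 4 and 331 in Dox+FRG Day 8, where matched lists would give 24.1 and 61.5. An effect of low oxygen on methylation, a faster loss among its possible forms, may be a candidate explanation, as a hypothesis only. The count of called tiles fell from 469 to 2 with the dispersion of the 4 compared libraries. With calls pooled over CpGs the mean difference changed sign.

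Tiles that were dense in CpGs and held 35 to 65% in all 13 groups were 739 in number. Of these, 11 were called in Dox+FRG Day 4, 32 in Dox+FRG Day 8, 90 in Dox+FRG Day 10, 206 in primary SCs and 75 in Dox Day 8 against Day 0, 154 and 158 in Dox+FRG Day 10 against primary and expanded SCs, and 2 in hypoxia against normoxia. Of all 232429 tested tiles the same comparisons called 6201, 18870, 27621, 59133, 13799, 49156, 47028 and 469, in that order. The limit of 35 to 65% in all groups also caps the differences that this set can show. Chromosome X calls relative to autosomal calls were 0.739 of the Day 0 value in primary SCs, 0.717 in expanded SCs, 0.719 in MEF10 MyoD+FRG and 0.730 in MEF10 MN+FRG, and 0.973 to 1.05 in the other MEF14 groups.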
